A study of Canis lupus familiaris with 4 samples.

How the data were processed

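ChIP-seq with a monoclonal antibody against TWIST1 was done on MDCK cells that express human TWIST1, with input chromatin from the same cells. Per the labels' protocols, cells were crosslinked in 1% formaldehyde for 10 min, chromatin was sheared by sonication, and unstranded TruSeq libraries were made. There were 2 TWIST1 libraries and 2 input libraries, in 2 independent experiments. The replicate numbers are those of the sample titles.

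Per the submitters' processing notes, the authors used Bowtie2, Picard and MACS2 and the genome build CanFam3.1. The versions of these tools, the filters and the pairing of input with ChIP libraries are not given in the sources used here. The deposited peak lists are in the narrowPeak format of MACS2, 1 list per TWIST1 library, so peaks were called on each library alone. The deposited fold enrichment is the ratio of the pileup at the summit to the expected local background, after MACS2 adds 1 to each. The deposited −log10 p and −log10 q are those of MACS2's Poisson test at the summit. The deposited score was the whole part of 10 times the −log10 p, and was not used further. The deposited summit offset, another unit, is a distance in bases from the start of the peak. The names given to the deposited lists carry a p of 0.05, while the lowest −log10 p values, 2.01 and 2.00, match a threshold of 0.01. The names of the deposited peaks carry the run number 2 for replicate 1 and 3 for replicate 2. Input libraries have no list of their own and were not used other than through the background in the peak statistics.

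The pileup and background at each summit were recovered by solving MACS2's formulas for fold enrichment and Poisson p together. The smallest background in a list was taken as its genome-wide background, below which MACS2 does not let the local background fall. The shortest peaks, 165 bp in replicate 1 and 162 bp in replicate 2, were taken as the fragment lengths. With these, the genome-wide backgrounds correspond to 12.3 and 26.7 ChIP tags per kb of effective genome in replicates 1 and 2. The backgrounds moved in steps of 0.59 and 0.689, taken as the scaling of the input, which corresponds to 20.8 and 38.8 input tags per kb. Total read numbers are not given in the sources used here.

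Consensus regions were the merged intervals of peaks with q ≤ 0.05 in both replicates that overlapped by at least 1 bp. Each region took its fold enrichment, p, pileup and summit in a replicate from the peak with the highest −log10 p there. Chance was measured with 1000 random placements of the replicate 2 peaks within the same chromosomes, up to the last peak of each, since no chromosome lengths or assembly gaps of this build were at hand. Overlap shares have exact binomial intervals at a confidence level of 95%. Pileups were compared between replicates with an exact binomial test per region, and the density of regions with an exact binomial test per chromosome, both with Benjamini-Hochberg adjustment. Ratios of densities have intervals from the exact binomial interval of the split of counts. The irreproducible discovery rate was computed with an own implementation of the copula mixture model. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, with seed 7.

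The computations were tested on simulated data. In 4555 simulated peaks, 100% of the pileups were recovered within 0.05. The count of shared peaks above chance was −0.7 with 0 planted sites and 1001 with 1000 planted sites. For the irreproducible discovery rate, the simulated share of reproducible pairs was recovered as 0.399, 92.0% of those pairs were called, and 5.69% of the calls were irreproducible. The simulated reproducible pairs had a correlation of 0.8, against 0.72 fitted in the data, and stood further apart from the other pairs. The shares of calls therefore do not carry over to the data. In the simulated comparison of pileups, 66% of 200 regions changed 2-fold were called, and 0.154% of 2600 unchanged ones. Most simulated summed pileups were larger than the median of 46 in the data, so the 66% does not carry over to the data.

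The thresholds for consensus regions, the measures of overlap and rank agreement, and the naming of regions were set before the data were examined. The rule named 10 consensus regions, those with the highest lower-of-the-replicates fold enrichment. It also named the nearest genes and genes of fixed lists, which could not be placed. The limits chosen after the data were seen were a background of at least 5 times the genome-wide value, the 250 kb zone at chromosome starts, the 10 kb distance between neighbours, the classes of fold enrichment, bins of 5 Mb with at least 30 peaks in each replicate, and the 2000 peaks of lowest p. The ratio of the folds between the replicates, the comparison of summits with random points, the test of pileups, the tests per chromosome, the comparison of the X with the autosomes and the attention to chromosomes 14 and 17 were also chosen then. Alternatives covered the threshold (a q of 0.01, or a p of 1e-5 in place of q), the overlap that counts as shared, the irreproducible discovery rate, each replicate alone, the measure of rank, and a chance model with local shifts.

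Planned analyses that need the sequence or gene annotation of CanFam3.1 were left out, since the reference at hand names genes on another assembly. These were the share of summits with an E-box (the CANNTG motif), the preference among E-box cores, the spacing of tandem E-boxes, other known motifs, E-boxes in shared against single-replicate peaks, the share of regions at promoters, and 13 lists of genes. Regions are therefore given by position and without gene names.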

Results

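TWIST1, a basic helix-loop-helix transcription factor that drives epithelial cells towards a mesenchymal state, was mapped by ChIP-seq in MDCK cells. MDCK is an epithelial line from dog kidney, and the cells used here carried human TWIST1 expressed all the time and had taken on a mesenchymal phenotype. The series title places the work in a search for genes that TWIST1 controls in the mesoderm of the head. The data set held 4 libraries: 2 immunoprecipitated with a monoclonal antibody against TWIST1 and 2 of input chromatin that had not been immunoprecipitated. Each kind of library came from 2 independent experiments, called replicates 1 and 2 below. Cells without the transgene, or chromatin precipitated with an unrelated antibody, were not analysed here, so a region enriched over input has not been set against cells lacking human TWIST1.

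Each TWIST1 library had its own list of peaks on the dog genome build CanFam3.1, and the input libraries entered only as the background of that peak calling. The list of replicate 1 held 73701 peaks and that of replicate 2 held 60370. Both were permissive lists, with lowest −log10 p values of 2.01 and 2.00. At q ≤ 0.05 there were 25036 peaks in replicate 1 (34.0% of its list) and 20333 in replicate 2 (33.7%). Peaks were short, with median widths of 197 bp in replicate 1 and 196 bp in replicate 2. The median fold enrichment over the local background was 3.05 in replicate 1 and 2.63 in replicate 2, and the highest was 34.3 and 20.8.

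The depth of the libraries was read from the peak statistics, since fold enrichment and p together fix the number of overlapping fragments at a summit (the pileup) and the background expected there. The pileups came out within 0.05 of a whole number in 100% of the peaks of both lists. The genome-wide background was 2.03 fragments per position in replicate 1 and 4.33 in replicate 2, a ratio of 2.14. The lowest pileup listed was 6 in replicate 1 and 10 in replicate 2, and the highest was 327 and 322. Intervals given below for fold enrichment are exact Poisson 95% intervals of the pileup at a fixed background, and cover counting error only.

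Strongly enriched sites were found in both experiments, and most weaker ones in a single experiment. The comparison asked which TWIST1 peaks recurred when the whole experiment was repeated. Overlapping peaks with q ≤ 0.05 in both replicates formed 2809 consensus regions, many more than chance placement of the peaks gave. They nevertheless took up a small part of each list. Of the 25036 such peaks in replicate 1, 14.2% (exact binomial 95% interval 13.7 to 14.6) overlapped a peak of any strength in replicate 2. In the other direction the share was 16.97% (16.5 to 17.5) of 20333.

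Random placement of the replicate 2 peaks along the same chromosomes gave a mean of 108 consensus regions (SD 10.3, highest of 1000 placements 144), so the observed count was 26.04-fold higher (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Random placement gave a shared percentage of 1.22% in replicate 1 and 1.46% in replicate 2, and the observed percentages were 11.6-fold higher in both (one-sided permutation p = 0.001 each). The numbers without a partner were 21489 peaks in replicate 1 and 16883 in replicate 2.

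Sharing fell steeply with rank. All 100 peaks of lowest p in each list had a partner in the other list. At ranks 101 to 500 a partner was found for 395 of 400 peaks of replicate 1 and 399 of 400 of replicate 2. The share was 90.6% and 94.8% at ranks 501 to 1000, and 67.0% and 63.4% at ranks 1001 to 2000, for replicates 1 and 2. It dropped to 27.0% and 21.7% at ranks 2001 to 5000 and to 4.84% and 6.70% at ranks 10001 to 20000. Past rank 40000 it was 2.95% and 3.86%, against 1.10% and 1.37% by random placement and 1.43% and 1.74% after local shifts.

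**Figure D1:**
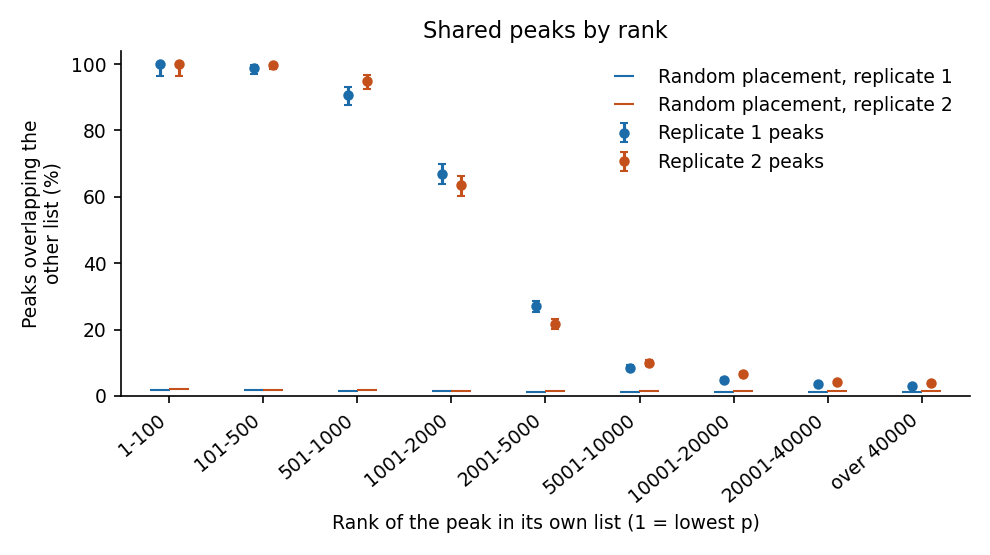
Percentage of peaks that overlapped a peak of the other replicate, by the rank of the peak in its own list; points are the observed shares with exact binomial 95% intervals, and dashes are the means of 1000 random placements. The share fell from 100% of the first 100 peaks to 4.84% and 6.70% at ranks 10001 to 20000.

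The consensus regions were mostly narrow sites of moderate enrichment. Replicate 1 gave the higher fold enrichment at most of them, and the summits of both replicates lay close together. The regions had a median width of 385 bp (184 to 2267 bp) and covered 1128 kb in total. Fold enrichment was at least 2 in both replicates at 2710 regions (96.5%) and at least 3 at 2168 (77.2%). It was at least 5 in both at 497 regions (17.7%), at least 10 at 47 (1.67%) and at least 15 at 5.

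The median fold enrichment of the consensus regions was 5.06 in replicate 1 (quartiles 3.797 and 7.01) and 3.59 in replicate 2 (quartiles 3.04 and 4.67). The log2 ratio of the folds, replicate 1 over replicate 2, had a median of 0.42 (SD 0.48 across regions), a 1.34-fold difference. Replicate 1 was higher at 2374 regions (84.5%). Among all peaks with q ≤ 0.05 the median fold was 3.64 in replicate 1 and 3.02 in replicate 2, so the difference was not particular to the consensus regions. At the 497 regions with fold enrichment of at least 5 in both, the median log2 ratio was 0.445, and replicate 1 was higher at 422. The part of the q threshold in this difference was not tested. The median pileups of the 2809 regions ran the other way, at 21 fragments in replicate 1 and 25 in replicate 2, over the higher background of replicate 2. Spearman's rho between the replicates was 0.58 for −log10 p and 0.56 for fold enrichment across the 2809 regions, and 0.63 and 0.60 across the 5014 overlapping pairs of peaks of any strength. Without the regions whose input background was at least 5 times the genome-wide value, rho was 0.58 for −log10 p and 0.50 for fold enrichment. These correlations are across regions, which are not independent replicates.

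Few individual regions could be called as different between the replicates. The regions had passed q ≤ 0.05 in both lists, which leaves out sites strong in a single replicate. An exact binomial test (two-sided, Benjamini-Hochberg adjusted over 2809 regions) compared each region's pileups with the split of the summed pileups, of which replicate 1 held 45.1%. At an adjusted p of 0.05 it called 0 regions as relatively higher in replicate 1 and 3 in replicate 2, and 230 regions had an unadjusted p under 0.05. The variance of the pileups about that split was 1.34 times the binomial variance. Among the 497 regions with fold enrichment of at least 5 in both replicates, adjusted over those regions alone, it called 0 and 2, with 49 at an unadjusted p under 0.05. At the median summed pileup of 46 fragments, the observed pileups had to differ 3.88-fold from the general split for a call as higher in replicate 1, and 4.57-fold for replicate 2. Regions with larger pileups needed less. The test compares 1 library with 1 library and describes those libraries.

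The summits of the replicates lay a median of 40 bp apart, against 105.2 bp for random points drawn evenly along the same overlapping peaks. A summit is the highest point of a pileup and need not fall evenly along its peak. The comparison therefore cannot show that summits lay closer than the overlap of the peaks alone would bring. The summits were within 50 bp at 59.2% of the regions and within 100 bp at 84.9%. The median distance was 29 bp at the 497 regions with fold enrichment of at least 5 in both replicates, and 45 bp at the 641 regions below 3 in either.

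**Figure D2:**
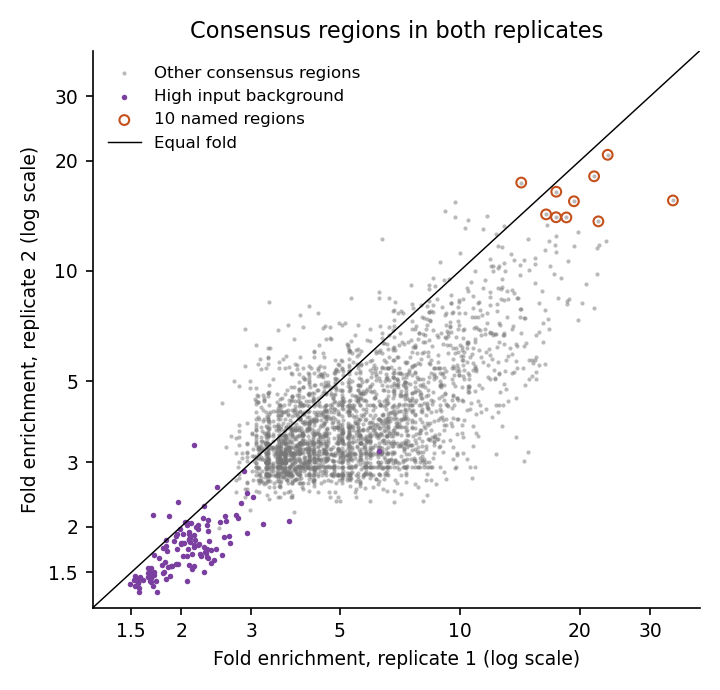
Fold enrichment over the local background in replicate 1 against replicate 2 at the 2809 consensus regions, both on log scales, with the line of equal fold. Circles mark the 10 strongest regions, and purple points the 121 regions where the input background was at least 5 times the genome-wide background in either replicate.

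The 10 strongest regions lay on 8 chromosomes and were enriched at least 13.7-fold in both experiments. They were taken by the lower of the 2 replicates' folds, a rule set before the data were examined. The first, at 9847135 to 9847825 on chromosome 22, was enriched 23.5-fold in replicate 1 (18.6 to 29.3) from a pileup of 78, and 20.8-fold in replicate 2 (17.3 to 24.8) from a pileup of 120, and had the lowest p of the replicate 2 list. The second, on chromosome 3 from 27932710 to 27933160, was enriched 21.7-fold (17.1 to 27.2) and 18.2-fold (14.8 to 22.1) in replicates 1 and 2. On chromosome 6, the region from 12336973 to 12337659 reached 17.5-fold (13.8 to 21.8) and 16.5-fold (13.3 to 20.2).

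The lowest p of the replicate 1 list belonged to the fourth region, at 4992545 to 4993285 on chromosome 14. Its fold enrichment was 34.3 in replicate 1 (28.2 to 41.2) and 15.6 in replicate 2 (12.97 to 18.6), and its pileups were 111 and 122, over local backgrounds of 2.27 and 6.89 fragments. The pileups did not differ from the general split (exact binomial test, two-sided, p = 0.430, adjusted over the 10 regions 0.815), so the gap in fold came with the background values.

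The other 6 regions were enriched between 14.3-fold and 22.3-fold in replicate 1 and between 13.7-fold and 17.4-fold in replicate 2. They lay on chromosome 16 (26870387 to 26870922), chromosome 2 (15236510 to 15237024), chromosome 3 (55105949 to 55106570 and 24348279 to 24349002), chromosome 24 (21069662 to 21070257) and chromosome 20 (39172414 to 39172910). Only the first of the pair on chromosome 3 had the higher fold in replicate 2, at 17.4 (14.1 to 21.4) against 14.3 (10.6 to 18.8). Its pileups of 48 and 92 did not differ from the general split after adjustment (exact binomial test, two-sided, p = 0.0107, adjusted over the 10 regions 0.107). In all 10 regions the replicates' summits lay between 1 and 70 bp apart.

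Some consensus regions lay where the input itself was piled up, and these were weakly enriched. The local background was at least 5 times the genome-wide background, in either replicate, at 121 regions (4.31%). Their median fold enrichment was 2.07 in replicate 1 and 1.74 in replicate 2, and their median background was 14.6 and 14.3 times the genome-wide value. Of the 121 regions, 86 lay within the first 250 kb of a chromosome, against 12 of the 2688 others. A single one was enriched at least 3-fold in both replicates, at 78307343 to 78307794 on chromosome 5, and was picked out after its values were seen. It reached 6.27-fold (5.21 to 7.49) in replicate 1 and 3.23-fold (2.63 to 3.92) in replicate 2, over backgrounds 9.04 and 7.0 times the genome-wide value.

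Consensus regions were more often close neighbours than random positions. Of the 2809 regions, 12.4% had another region within 10 kb, against 2.54% at random positions on the same chromosomes (SD 0.41, highest of 1000 draws 3.84; one-sided permutation p = 0.001, the smallest possible). Without the 121 regions of high input background the share was 9.45% against 2.45% at random (one-sided permutation p = 0.001). As a share of the set, the excess was smaller in each replicate alone. All peaks with q ≤ 0.05 gave 24.5% against 19.7% at random without replicate 2, and 22.6% against 16.4% without replicate 1. Those sets held 25036 and 20333 peaks against 2809 regions, so the shares come from sets of unlike density.

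The regions were spread unevenly over the chromosomes, and the X chromosome held few of them. Over the 39 chromosomes, which spanned 2326 Mb up to their last peak, there were 1.21 consensus regions per Mb. An exact binomial test (two-sided, Benjamini-Hochberg adjusted over 39 chromosomes) called 7 chromosomes, 3 of lower and 4 of higher density than the genome. It treats regions as independent, although neighbouring regions are not.

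The X chromosome had 45 regions, or 0.364 per Mb (exact Poisson 95% interval 0.265 to 0.486; adjusted p = 1.08e-22). Chromosome 15 (0.764 per Mb, exact test, adjusted p = 0.00509) and chromosome 22 (0.830 per Mb, adjusted p = 0.0349) were the other 2 of lower density. Density was higher on chromosome 17 (1.80 per Mb, 116 regions), chromosome 5 (1.72, 153 regions), chromosome 9 (1.72, 105 regions) and chromosome 37 (1.78, 55 regions). Fold enrichment was at least 5 in both replicates at 15 regions of chromosome 17 (64.3 Mb), 29 of chromosome 5 (88.9 Mb), 30 of chromosome 9 (61.1 Mb) and 7 of chromosome 37 (30.9 Mb). The autosomes held 0.222 such regions per Mb, so the excess of chromosome 17 lay mainly in weaker regions. Chromosome 17 also had the most listed peaks per Mb, 42.0 in replicate 1 and 37.5 in replicate 2. On chromosome 37, 18 of the 55 regions had high input background, and without such regions its density of 1.198 per Mb was no longer called (exact test, adjusted p = 0.822). Chromosome 34, at 0.689 per Mb without them, was then called as lower (exact test, adjusted p = 0.0174).

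The X held 0.290 times the autosomal density of consensus regions (0.211 to 0.389), with 45 regions on the X and 2764 on the autosomes, where single chromosomes ranged from 0.712 to 1.80 per Mb. Among regions with fold enrichment of at least 5 in both replicates the ratio was 0.291 (0.125 to 0.578), from 8 regions on the X. The full peak lists showed no such deficit, with X to autosome ratios of 1.201 in replicate 1 and 1.2004 in replicate 2, and peaks with q ≤ 0.05 gave 1.016 in replicate 1 and 1.101 in replicate 2. Among the 2000 peaks of lowest p in each list, the ratio was 0.308 (0.212 to 0.431) in replicate 1 and 0.494 (0.369 to 0.647) in replicate 2.

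**Figure D3:**
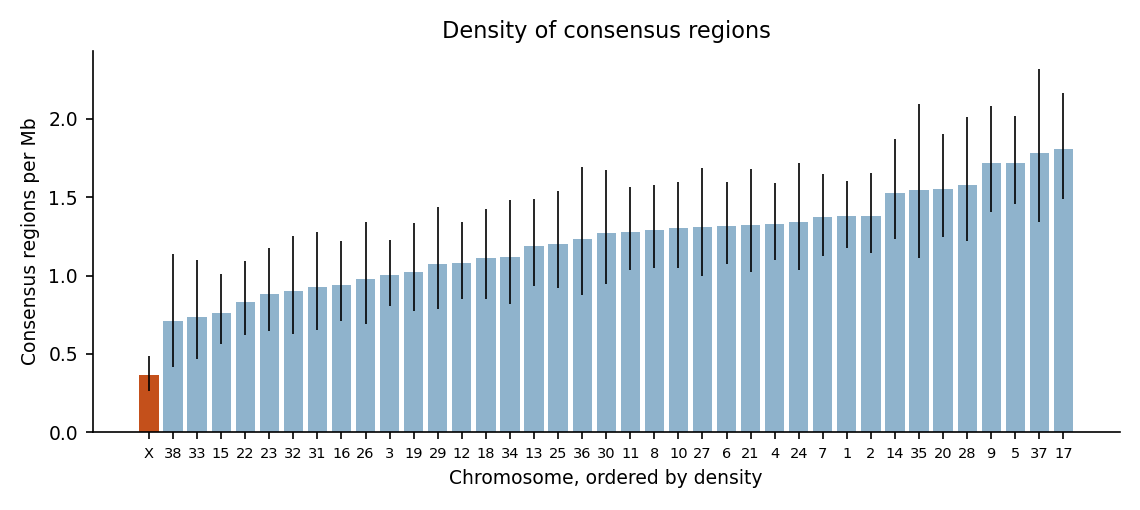
Consensus regions per Mb of each chromosome, in order of density, with exact Poisson 95% intervals. The X chromosome (0.364 per Mb) was the lowest and chromosome 17 (1.80 per Mb) the highest.

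The background at the peaks, which came from the input, stood higher along nearly all of chromosomes 14 and 17 than along most of the genome. It cannot fall below the genome-wide value, where 29.6% of replicate 1 peaks and 25.7% of replicate 2 peaks lay. Stretches of lower input would therefore not show. Single 5 Mb bins of the other chromosomes reached 1.39 times that value in replicate 1 and 1.41 in replicate 2. In multiples of the genome-wide background, the median over the peaks of chromosome 14 was 1.49 in both replicates, and that of chromosome 17 was 1.501 in replicate 1 and 1.508 in replicate 2. The median of the other chromosomes was 1.10 and 1.08, and the highest of them reached 1.17 in replicate 1 (chromosomes 11 and 37) and 1.16 in replicate 2 (chromosome 11). In 471 bins of 5 Mb, Spearman's rho between the replicates' backgrounds was 0.87, and 0.85 without chromosomes 14 and 17, across bins that are not independent replicates. Which input library served which peak list is not given in the sources used here. The recovered input depths were 20.8 and 38.8 tags per kb of effective genome for replicates 1 and 2, which a single input used in full for both lists would not give.

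**Figure D4:**
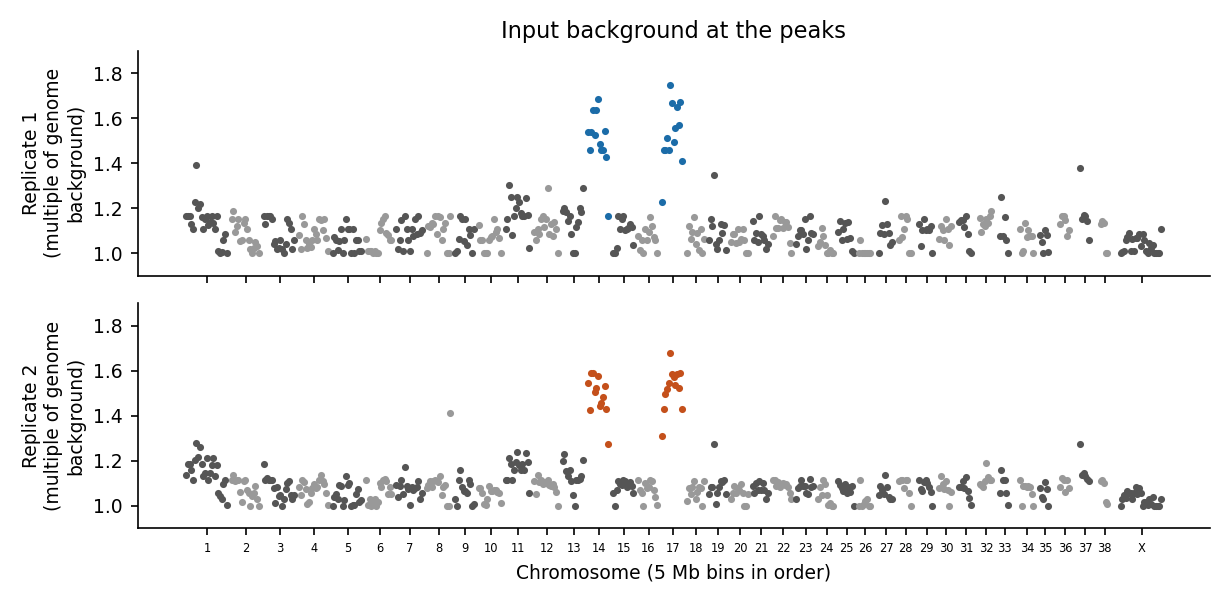
Median background at the peaks in 5 Mb bins along the genome, in multiples of the genome-wide background, for replicate 1 (top) and replicate 2 (bottom). Chromosomes 14 and 17, in colour, lie between 1.17 and 1.75 in replicate 1 and between 1.27 and 1.68 in replicate 2.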

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

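The tests in this part were all chosen after the raised background had been seen. The signal lies in the input, which the comparisons of TWIST1 peaks use only as a reference. In multiples of the genome-wide background, the median at the peaks was 1.491 (replicate 1) and 1.491 (replicate 2) on chromosome 14, and 1.501 and 1.508 on chromosome 17, above the 1.17 and 1.16 reached by the highest of the other chromosomes. Which input library served which peak list is not given in the sources used here. The recovered input depths were 20.8 and 38.8 tags per kb of effective genome for replicates 1 and 2, which a single input used in full for both would not give.

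A few loci with very high input are argued against, since 25 of the 26 bins of 5 Mb on these chromosomes in replicate 1, and 26 in replicate 2, lay above the 95th percentile of the other bins (1.18 and 1.19). Extra copies of both chromosomes in the cell line may be the source, but cannot be told apart from other causes. The lowest bin, at 1.166 on chromosome 14 in replicate 1, was above the median of the other bins (1.09) and below their highest (1.39). Base composition or mappability of these chromosomes could also raise the input, and the 1.36-fold excess of chromosome 14 over the median of the other chromosomes in replicate 1 could not be corrected for sequence. No group of the design gives a biological explanation, and no copy number of the cells was measured. The higher density of consensus regions on chromosome 17 may be affected by the same source, while chromosome 14 (1.53 per Mb) was not called after adjustment (exact binomial test, adjusted p = 0.0876).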

How the results depend on the processing

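The settings chosen after the data were seen were the set without high input background, the local shifts, the autosomes without chromosomes 14 and 17, and all settings for the X ratio, the fold ratio, the regions with fold of at least 5 (479 to 497), the share of neighbouring regions, and the alternatives for the planned rank agreement within the regions (0.477 to 0.587). The count of 2809 consensus regions ranged from 1919 (irreproducible discovery rate ≤ 0.05) to 2688 (no high input background) under the alternatives that keep both replicates, and all 10 named regions were kept in each. Every region of these alternatives overlapped the 2809 regions, and the named regions had been picked for high fold in both replicates. Their being kept is therefore no independent support. The ranges of the X ratio, the fold ratio and the regions with fold of at least 5 likewise come from sets nested in the main one. Each replicate alone gave 20333 to 25036 regions, as a single list is not filtered by the other. The X to autosome ratio stayed between 0.275 and 0.296 in the sets that need both replicates, but was 1.016 to 1.101 in each replicate alone, so the deficit depends on the filter by both replicates or on strength. The median log2 fold ratio stayed between 0.42 and 0.50. Rank agreement over all pairs was 0.63 by −log10 p and 0.60 by fold enrichment; the cause was not tested. The share of replicate 1 peaks with a partner ranged from 11.2% (q ≤ 0.05 in both lists) to 26.7% (q ≤ 0.01), and that of replicate 2 from 13.9% to 34.7%, all above chance. With local shifts of 20 to 200 kb as chance, 130 consensus regions were given by chance. In all, 47 values were counted as kept, 4 moved and 2 reversed. Tests were kept by direction and side of the threshold, counts by a fixed fold limit, and rank agreement by an interval from resampling. The limit for counts was wide enough to keep 1919 against 2809 regions. Under local shifts only the chance level differs, so the observed values there stayed the same by construction. No paired analysis was possible because the input libraries have no peak list, and the deposited peak statistics already set each ChIP library against input. The alternatives for E-boxes, promoters, gene lists and shared against single-replicate peaks were not run, for lack of a matching reference. No peak had a pileup under 6 fragments in replicate 1 or 10 in replicate 2, so weaker sites cannot be read from the lists.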

Other observations

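All tests of explanations in this part were chosen or changed after the results were seen, and the test of too few tags, first set for both replicates together, was then split by replicate and widened by counting error. Most peaks with q ≤ 0.05 had no partner in the other replicate. Too few tags in the other library cannot be told apart from other causes. Scaled by the 1.495-fold difference between the replicates at consensus regions, the median pileup over background of unpaired peaks was 3.24 from replicate 1 and 5.18 from replicate 2, against typical listed levels of 3.23 in replicate 2 and 4.44 in replicate 1. These peaks were picked for high counts and the scaling came from paired ones, and at the lower Poisson bounds of the pileups the lower quartiles were 1.45 and 2.83, under those levels. A selection of high counts from the chance spread of many positions may account for part of them, and the 4.84% of replicate 1 peaks at ranks 10001 to 20000 with a partner, against 1.48% after local shifts, leaves that open. No biological explanation was tested, since both replicates had the same cells and treatment.

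The X chromosome held few consensus regions. Of the technical explanations tested, fewer listed peaks and lower input background at the peaks are both argued against. Chromosome 26, with a background of 1.00 in both replicates against 1.03 for the X, had 2.69 times the density of the X (1.70 to 4.23). The background cannot fall below the genome-wide value, so a lower input on the X would not show and the comparison cannot decide on coverage. Fewer listed peaks of any strength would lower the X in the full lists, where its ratio to the autosomes was 1.201 in replicate 1 and 1.2004 in replicate 2. Mappability and gene content of the X could not be examined, so these stay open. That TWIST1 may bind fewer strong sites on the X remains a hypothesis, and no group of the design tests it.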
